A study of Triticum aestivum with 12 samples.

How the data were processed

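Total RNA from seedling roots was amplified, labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels. The labels give 4 groups of 3 biological replicates: the control at 0 h in water of pH 6.5, 2 h at pH 4.0, 2 h at pH 10.0 and 24 h at pH 10.0. The arrays were read with Agilent Feature Extraction 10.7.3.1, per the file headers (version 10.7 per the submitters' processing notes). The processed signal used here is an intensity from which, per the file headers, the software had subtracted background, and it was not normalized between arrays. The other deposited columns used were the median spot and background intensities and the software's marks of 0 or 1 for spots well above background, outlier spots and saturated spots. No probe other than the controls counted as saturated on any of the 12 arrays, after the marks of repeat spots were averaged. Control spots, spike-ins included, were not counted.

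The authors also deposited a table of log2 values for the same arrays. Every column holds nearly the same set of values (a median of 7.265 in each), as after quantile normalization, and each correlates at 0.998 to 1 with the log2 processed signal of its array. The scale is therefore log2, values were not centred per probe, and a larger value means more signal. The software and exact steps behind that table are not given in the sources used here, and it served as an alternative.

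Each array held 45220 spots, of which 43803 were not controls and belonged to 43603 probes. Outlier spots were set to missing (70 values after averaging), repeat spots of a probe were averaged as log2 values, and the array's 75th percentile of the log2 processed signal was subtracted. Probes well above background on at least 3 of the 12 arrays were tested, 30536 in all, and 8866 probes were never well above background. Fold changes and adjusted p-values come from 1 limma 3.58.1 fit of the 4 group means to all 12 arrays in R 4.3.3 (lmFit, contrasts.fit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the probes tested in each of the 5 comparisons. A probe was called changed at an adjusted p under 0.05, and raised or lowered refers to such calls. Values after ± are SE for fold changes and SD for group levels. Tables were read with the R package data.table (version 1.17.8) and figures drawn with matplotlib 3.10.9 and pandas 2.3.3.

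The choice of test, filter, alternatives and rule for naming probes was made before the data were examined. That rule took the largest log2 fold changes among probes with an adjusted p under 0.05, well above background on all 3 arrays of a group and with no overlap between the 2 groups. Chance gives 10% of probes no overlap with 3 against 3 arrays. The rule also asked for a described gene product, and 35 gene lists with markers of other tissues were fixed for testing as sets. None of these could be used. The arrays name each probe by a sequence accession or, for 965 probes, by the probe's own ID. Of 40253 accessions 0 matched the reference table of 155467 wheat genes, so no list had a member and no gene name was used. Instead 2 raised and 2 lowered probes are named per comparison by the rest of the rule. The preset rule named more probes each way, and the number was cut because no gene name was available. Of 2147 accessions with at least 2 tested probes, none had probes called in opposite directions in 4 of the comparisons, and 1 did at 24 h against the control. Only accessions with at least 2 changed probes could differ. Against the control these were 173 for 2 h at pH 4.0, 80 for 2 h at pH 10.0 and 292 for 24 h at pH 10.0. They were 1 for pH 10.0 against pH 4.0 at 2 h and 235 for 24 h against 2 h at pH 10.0.

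Where a probe was not well above background on any array of the dimmer group, the fold is a lower limit, given as at least N-fold. It sets the mean of the brighter group against the mean, over arrays of the dimmer group, of the higher of the probe's own signal and the lowest signal of any probe well above background. Signal over background limits the array measurements in place of read depth.

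The arrays came from 3 slides of 4, scanned on 1 day in slide order. Slide and replicate number were the same thing, each slide held 1 array of every group, and values are therefore given within slides and with the slide as a block. The correlation of same-numbered arrays, after subtraction of group means, was between -0.188 and 0.437 over the 18 pairs.

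Overlaps between comparisons with the same controls were set beside 50 simulations of unchanged groups against those controls and beside the overlap of independent lists. The calling procedure was tested on simulated data with 200 changed probes among 30536, and recovered 55.5% to 65.7% of 2-fold changes, depending on the comparison, and 86.1% to 88.8% of 4-fold changes. It recovered 13.1% to 18.5% of 1.5-fold changes, so small differences were mostly out of reach with 3 arrays per group. Spike-in offsets were compared with an exact permutation test of 3 control against 9 treated arrays, and again with the control label permuted within slides.

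As a reference for equal signs among called probes, effects of the observed sizes were placed on probes at random, separately for each treated group, in 20 simulations with shared controls. This was done with the fold changes of called probes only and with all fold changes, and the higher share is given. Probes called the same way in acid and 2 h alkaline water numbered 49 to 68 with the former and 1198 to 1322 with the latter. The latter gave 8065 acid calls on average, so these numbers were not used for probes called the same way. For probes called opposite ways the numbers of both are given. Covariances free of shared arrays were taken between changes from the control within different slides, 6 pairs of slides per pair of comparisons.

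Alternatives tried were normexp background correction (offset 50), quantile and median scaling, the deposited table, other filters on dim probes, the slide as a block, fits to 6 arrays, an intensity trend, array quality weights, stricter thresholds and leaving out each array. The normexp run was planned on mean spot signals and used median signals, because a mean signal column was not among the data analysed here. Scaling to spike-in RNA, leaving out slide 2, the effects placed at random, the covariances within different slides and the permutation within slides were added after seeing the data.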

Results

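RNA levels were measured in the roots of wheat (Triticum aestivum) seedlings of the variety Bainongaikang 58, known as AK58. Seedlings were raised in deionized water of pH 6.5 to the stage of 1 leaf and then moved to water of pH 4.0 or pH 10.0. Roots were taken before the change (0 h, the control), after 2 h at pH 4.0, after 2 h at pH 10.0 and after 24 h at pH 10.0. Each of the 4 groups held 3 arrays, which the labels call separate biological replicates, so 12 arrays were compared, each with 43603 probes for wheat sequences. Between 64.5% and 71.7% of the spots on an array were well above background, and the 75th percentile of the processed signal lay between 1017 and 1641 intensity units. Arrays of 1 group correlated across probes at 0.972 to 0.989. The number of arrays per group limits the precision of each value, with a median standard error of a log2 fold change of 0.16 over the 30536 probes tested.

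In a principal component analysis, the component with the most variance (27.5%) set the 3 arrays of 24 h at pH 10.0, at scores of 56.6 to 89.6, apart from the 9 others, at -63.8 to -1.31. The files do not pair the probes with gene names, so the changes are given by probe ID and the sequence accession printed on the array design. No untreated roots of 2 h or 24 h were analysed here, so the change of water and the time since 0 h cannot be told apart in a comparison with the control. Each slide carried 1 array of every group, and each group had the same place on all 3 slides, so place and group cannot be told apart either.

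The comparison of 2 h at pH 4.0 with the control asked which transcripts responded early to acid water. Of the 30536 probes tested, 3680 changed at an adjusted p under 0.05, with 1742 raised and 1938 lowered. The raised probes moved further. At least 2-fold changes numbered 893 raised against 256 lowered, at least 4-fold changes 290 against 31, and at least 8-fold changes 96 against 3. The median log2 fold change was 1.02 among raised probes and -0.57 among lowered probes. In all, 41 probes were well above background on all 3 acid arrays and on no control array, and 39 of them were called raised. The reverse held for 154 probes, of which 31 were called lowered.

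Probe A_99_P462152 (CN011234) was 1 of the 2 raised probes named for this comparison. It was not well above background on any control array (log2 signal relative to the 75th percentile of -8.80 ± 0.585, SD, n = 3) and reached -2.36 ± 0.36 in acid, at least 22-fold higher, with an adjusted p of 3.8e-05. Probe A_99_P456107 (TC407830) went from -7.71 ± 0.70, not well above background on any control array, to -1.64 ± 0.57, at least 36.1-fold higher (adjusted p of 9.5e-05). With normexp, whose offset narrows changes of dim probes, the log2 changes of the 2 probes were 1.84 and 2.30. Both were also called raised after 2 h at pH 10.0. Probe A_99_P179251 (CA622242) fell from -4.87 ± 1.8 to a signal not well above background on any acid array, at least 2.31-fold lower (adjusted p of 0.014). The limit was 1.17-fold without control replicate 2 and 3.97-fold without control replicate 3. Probe A_99_P414732 (TC376280) fell from -4.54 ± 2.12 in the same way, at least 2.92-fold lower, with an adjusted p of 0.04 that was lost without 4 of the 6 arrays in turn and a limit of 1.26-fold without control replicate 2 and 4.84-fold without control replicate 1. With normexp both lowered probes lost their calls, at log2 changes of -1.05 (adjusted p of 0.28) and -0.98 (0.39).

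Within slides 1, 2 and 3 the 1742 raised probes had median log2 changes of 1.02, 0.985 and 1.03, and the 1938 lowered probes of -0.64, -0.44 and -0.61. Here and in the later comparisons, these probes were called from the same arrays, so a like direction on each slide is no separate evidence. With the slide as a block, 3999 probes changed. The count fell to 2104 without control replicate 1, 1840 without control replicate 3, 2204 without acid replicate 1 and 1759 without acid replicate 3. Raised probes outnumbered lowered ones without control replicate 1 (1225 and 879) or 3 (1066 and 774) and with normexp (951 and 810). They did not without control replicate 2 (1370 and 1477), so the more frequent direction changed with the alternative. Scaling the arrays to spike-in RNA instead of the 75th percentile put the median of all probes at -0.35, against -0.02, and left 471 raised and 635 lowered.

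**Figure D1:**
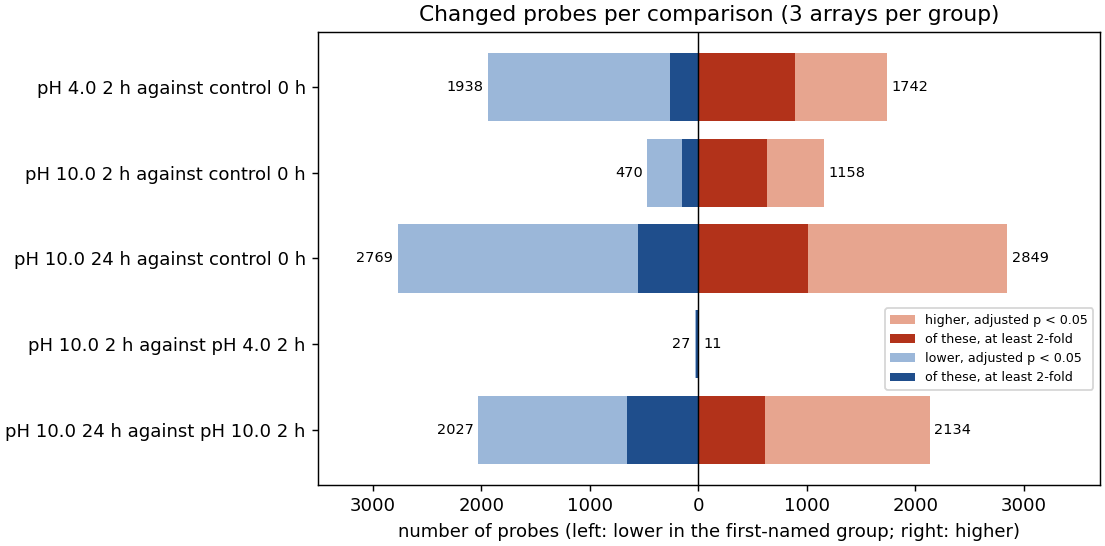
Number of probes changed at an adjusted p under 0.05 in each of the 5 comparisons, with probes lower in the first-named group drawn to the left and higher ones to the right, and darker bars for changes of at least 2-fold. The bars run from 11 higher and 27 lower probes between pH 10.0 and pH 4.0 at 2 h to 2849 higher and 2769 lower probes between 24 h at pH 10.0 and the control.

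The comparison of 2 h at pH 10.0 with the control asked the same of alkaline water. It changed 1628 probes, of which 1158 were raised and 470 lowered. At least 2-fold changes numbered 634 raised and 147 lowered, and at least 8-fold changes 36 and 3. The median log2 fold change was 1.06 among the raised and -0.76 among the lowered probes. Probe A_99_P145030 (CJ907973) rose from -4.64 ± 0.29 to 1.61 ± 0.14 (SD, n = 3), a log2 fold change of 6.25 ± 0.56 (SE, adjusted p of 0.00046), and it stood at 1.33 ± 0.25 in acid. Probe A_99_P042716 (CA486702) fell by 3.67 ± 0.28 on the log2 scale (adjusted p of 2e-04), from a signal close to the 75th percentile (-0.03 ± 0.39) to -3.70 ± 0.34.

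Probe A_99_P150147 (CJ851780) was raised by log2 5.87 ± 1.37 (adjusted p of 0.038), but only 1 of its 3 control arrays was well above background, the call was lost without 5 of the 6 arrays in turn and the log2 change ranged from 4.82 to 7.88 over left-out arrays. Probe A_99_P179251, lowered in acid, was lowered in alkaline water too, at least 2.23-fold (adjusted p of 0.026), a call lost without 4 of the 6 arrays in turn, with a limit of 1.13-fold without control replicate 2 and 3.83-fold without control replicate 3.

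On slides 1, 2 and 3 the raised probes had median log2 changes of 0.81, 1.18 and 1.13, and the lowered probes of -0.80, -0.68 and -0.775. With the slide as a block, 1907 probes changed. The count was 963, 945 and 724 without control replicates 1, 2 and 3, 882 without alkaline replicate 2 and 685 without alkaline replicate 3. The excess of raised over lowered probes (71.1% raised) turned round under spike-in scaling, which gave 209 raised and 373 lowered (35.9% raised) with the median of all probes at -0.498.

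Most probes that changed at 2 h in alkaline water had changed the same way in acid water. The 2 comparisons shared 820 raised and 312 lowered probes, 1132 in all, and 1 probe changed in opposite directions. Independent lists of these sizes would share 66.1 raised and 29.8 lowered probes. In 50 simulations of unchanged groups against the same controls 0 probes were shared in this and the other pairs of comparisons, but such groups give next to no calls, so that number says nothing about the shared controls. Part of the excess of shared probes over independent lists may come from the 3 shared control arrays, which are too few to split with at least 2 on each side. Across probes, the fold changes correlated at 0.716, against 0.501 in the simulations, and their covariance was 0.21, against a simulated 0.0525, a difference of 0.157. With acid and alkaline changes taken within different slides, so that no array was shared, the 6 covariances were 0.12 to 0.267. The correlations were then 0.23 to 0.501, and 47.2% to 72% of all probes had the same sign. Of the 4175 probes changed in either comparison, 96.2% had the same sign in both, where effects of the observed sizes placed on probes at random gave at most 57.1%, shared controls included. Over all probes tested the share was 70.9%, against 66.7% in simulations of unchanged groups. Such groups hold no effects, so that share and the simulated correlation are no reference for groups that changed. The number shared fell to 692, 711 and 535 without control replicates 1, 2 and 3, to 717 and 580 without alkaline replicates 2 and 3, and to 725 without acid replicate 3. It was 1288 with the slide as a block. Under spike-in scaling 160 raised and 199 lowered probes were shared, so the excess of raised probes turned round.

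**Figure D2:**
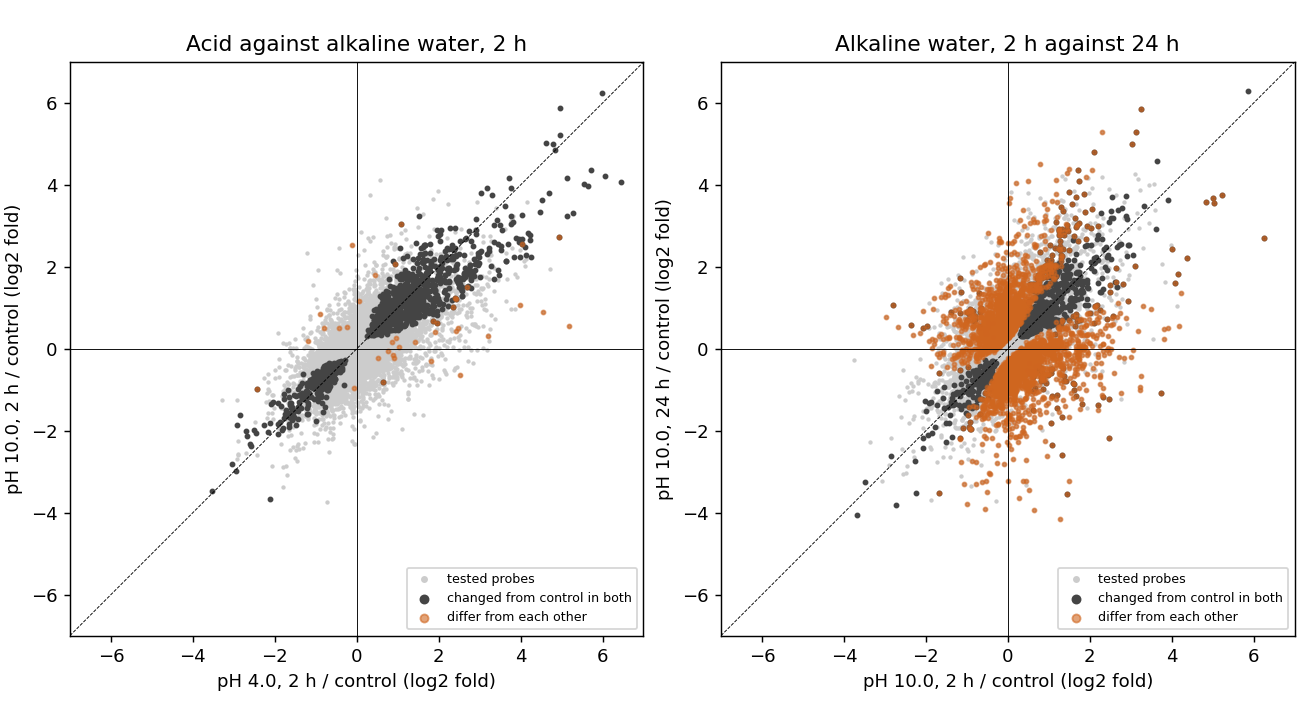
Log2 fold changes against the control for each tested probe, with 2 h at pH 4.0 against 2 h at pH 10.0 on the left and 2 h against 24 h at pH 10.0 on the right, dark points for probes changed from the control in both and orange points for probes that differ between the 2 groups plotted. On the left 1132 probes changed the same way and 38 differed directly, and on the right 754 changed the same way and 4161 differed.

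The direct comparison of pH 10.0 with pH 4.0 at 2 h asked where the 2 responses differed. It called 38 probes, 11 higher in alkaline and 27 higher in acid water, 30 of them by at least 2-fold. Probe A_99_P312616 (TA85402_4565) was well above background only in acid, at -3.24 ± 0.31 (SD, n = 3). It was at least 6.95-fold lower in alkaline water (adjusted p of 0.0042) and also not well above background on any array of the other two groups. Probe A_99_P312611 (TA85401_4565) followed it, at -2.46 ± 0.33 in acid and at least 11.5-fold lower in alkaline water (adjusted p of 0.025, lost without 5 of the 6 arrays in turn). In the other direction, probe A_99_P568882 (BE444013) was well above background only at 2 h in alkaline water, at least 1.59-fold higher than in acid (adjusted p of 0.013, lost without 2 of the 6 arrays in turn). Probe A_99_P084200 (CV767831) was higher in alkaline water by log2 1.96 ± 0.28 (SE, adjusted p of 0.04), and the call was lost with the slide as a block (adjusted p of 0.058, and 0.053 to 0.17 over the alternatives that ended it) and without 5 of the 6 arrays in turn.

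The number of direct differences changed with single arrays. Without alkaline replicate 1 the test called 1030 probes (630 higher in alkaline water, 400 higher in acid), all 38 among them. Without alkaline replicate 2 it called 1, without alkaline replicate 3 it called 3, without acid replicate 1 it called 1 and without acid replicate 3 it called 8. Over all 12 arrays, the 95% interval of the difference between alkaline and acid water lay within 2-fold for 78.6% of the probes tested. An unadjusted p under 0.05 (limma) was found for 5189 of 30536 probes. With no difference, chance gives a share of 0.05 on average. Within slides 1, 2 and 3 the 11 probes higher in alkaline water had medians of 1.30, 1.37 and 1.36 and the 27 lower ones of -1.39, -1.46 and -1.23. These 38 probes were called from the same arrays, so like medians among slides were built into the calls. With the slide as a block, 53 probes differed. No probe was called with normexp background correction or without slide 2, and array quality weights called 9046.

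**Figure D3:**
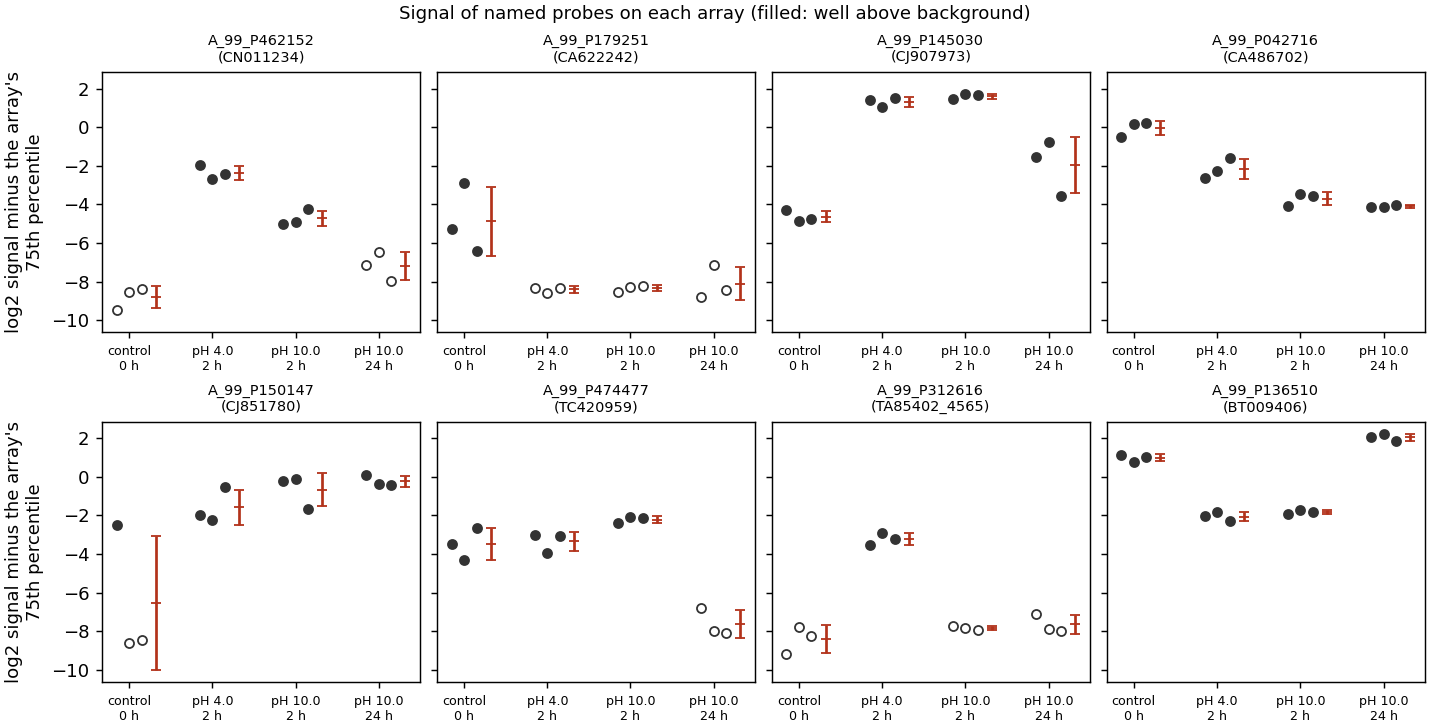
Log2 signal minus the array's 75th percentile for 8 named probes on each of the 12 arrays, with filled points for spots well above background, open points for the others, and bars for the mean and SD of 3 arrays. A_99_P312616 is filled only at pH 4.0, and A_99_P145030 stands at 1.33 and 1.61 in both 2 h groups against -4.64 in the control.

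The comparison of 24 h at pH 10.0 with the control asked what remained or appeared after a day in alkaline water. It changed 5618 probes, 2849 raised and 2769 lowered. At least 2-fold changes numbered 1008 raised and 553 lowered, and at least 8-fold changes 77 and 26. Median log2 fold changes were 0.75 and -0.64. Probe A_99_P519567 (CD865902) rose by log2 5.86 ± 0.28 (SE, adjusted p of 2.7e-05), from -3.83 ± 0.48 to 2.04 ± 0.10 (SD, n = 3), after rises of 4.03 ± 0.28 at 2 h in acid and 3.26 ± 0.28 at 2 h in alkaline water. Probe A_99_P150147 was raised by 6.30 ± 1.37 (adjusted p of 0.013), with 1 of 3 control arrays well above background, a range of 5.26 to 8.32 over left-out arrays and a call lost without 2 of the 6 arrays in turn. Probe A_99_P042716 fell by 4.07 ± 0.28 on the log2 scale (adjusted p of 6.8e-05), with no difference called from its level at 2 h. Probe A_99_P474477 (TC420959) went from -3.48 ± 0.83 to a signal not well above background on any 24 h array, at least 6.59-fold lower (adjusted p of 0.00055).

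Within slides 1, 2 and 3 the raised probes had medians of 0.60, 0.93 and 0.70 and the lowered probes of -0.50, -0.79 and -0.60, and 6090 probes changed with the slide as a block. The count was 2825 without control replicate 2, 2750 without control replicate 3 and 2555 without replicate 2 of 24 h. Under spike-in scaling 491 probes were raised and 1311 lowered (27.2% raised, against 50.7%), with the median of all probes at -0.32.

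The 24 h response shared 554 raised and 200 lowered probes with the 2 h alkaline response, where independent lists would share 108.0 and 42.6, while 82 probes had turned round. Under spike-in scaling these were 83 raised and 136 lowered, more lowered than raised, and 8 that had turned round. It shared 495 raised and 469 lowered probes with the acid response (101 and 110 under spike-in scaling), where independent lists would share 162.5 and 175.7, while 302 probes went in opposite directions (171 raised in acid and lowered at 24 h, 131 the reverse). Called effects placed at random gave 138 to 181 opposite probes for acid and 24 h and 56 to 98 for the alkaline times. All effects placed at random gave 1443 to 1536 and 1171 to 1303. The covariance of fold changes exceeded the simulated one by 0.115 for the 2 alkaline times and by 0.0722 for acid and 24 h. For the alkaline times the correlation was 0.52, against 0.499 in simulations of unchanged groups, and 67.1% of probes had the same sign, against 66.6%. For acid and 24 h the correlation was 0.343, against 0.501, and 54.9% had the same sign, against 66.7%. Unchanged groups hold no effects, so these simulated correlations and shares are no reference for groups that changed. With effects of called probes placed at random the covariances were 0.04651 to 0.05788 for acid and 24 h, against 0.125 observed. For the alkaline times they were 0.04815 to 0.05511, against 0.167. Of probes called in either comparison, 63.0% had the same sign for acid and 24 h, against at most 56.3%. Within different slides the covariances were 0.0818 to 0.171 for the alkaline times and 0.0333 to 0.172 for acid and 24 h. The shares of all probes with the same sign were then 44.3% to 65.8% and 42.5% to 64.8%. In all 3 treated groups, 346 probes were raised and 117 lowered, and the 346 had median log2 changes of 1.19, 1.25 and 1.27 in acid, 2 h alkaline and 24 h alkaline water. Left-out arrays took the same-way count with the 2 h alkaline response from 754 to as few as 314 (without control replicate 3), with 471 and 393 without control replicates 1 and 2 and 390 and 324 without 2 h alkaline replicates 2 and 3. The same-way count with acid went from 964 to 614, 551 and 402 without control replicates 1, 2 and 3, 578 without replicate 2 of 24 h and 500 without acid replicate 3. The 346 probes ranged from 173 to 378 and the 117 from 31 to 125 over left-out arrays, and they were 59 and 62 under spike-in scaling, 132 and 46 with normexp and 92 and 37 without slide 2.

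The comparison of 24 h with 2 h at pH 10.0 asked how the alkaline response moved with time. It called 4161 probes, 2134 higher and 2027 lower at 24 h, of which 615 and 656 differed by at least 2-fold. Under spike-in scaling 587 were higher and 384 lower (60.5% higher, against 51.3%). Probe A_99_P136510 (BT009406) fell early and recovered. It stood at 0.99 ± 0.18 in the control, -2.05 ± 0.24 in acid, -1.82 ± 0.12 after 2 h in alkaline water and 2.06 ± 0.185 at 24 h (SD, n = 3), a difference of log2 3.88 ± 0.15 between the alkaline times (SE, adjusted p of 6.5e-06), and at 24 h it was above the control by 1.07 ± 0.15 (adjusted p of 0.0019). Probe A_99_P318681 (TA87143_4565) changed late. It was at -2.30 ± 0.26 in the control and -2.10 ± 0.44 at 2 h, and at 1.75 ± 0.29 at 24 h, a rise of 3.84 ± 0.35 (adjusted p of 0.00031). Probe A_99_P556347 (TC454715) rose by 1.43 ± 0.28 at 2 h and then fell by 4.97 ± 0.28 on the log2 scale between 2 h and 24 h (adjusted p of 2.8e-05), to a level below the control. Probe A_99_P474477 was at least 15.9-fold lower at 24 h than at 2 h (adjusted p of 0.00022).

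Of the 1158 probes raised at 2 h in alkaline water, 437 were lower at 24 h than at 2 h and no longer raised. Their median log2 change went from 1.13 to -0.02, and 377 of them had also been raised in acid. The choice of probes not raised at 24 h held that later median down, and 50 of the 437 were called lowered at 24 h. Another 404 of the 1158 were raised at both times with no difference called between them, and 114 were raised at both times and higher at 24 h. Of the 470 probes lowered at 2 h, 158 were higher at 24 h and no longer lowered, and 200 were lowered at both times. Of the 158, 32 were called raised at 24 h. The 437 and the 158 are called returning probes, although these 50 and 32 had passed the control level and are the 82 that turned round. A late set, called at 24 h and not at 2 h and different between the times, held 1114 raised probes (median log2 change of 0.01 at 2 h and 0.73 at 24 h) and 949 lowered probes (-0.02 and -0.72). The 2 h arrays entered both tests behind the sets of returning probes and the 24 h arrays both tests behind the late sets, so chance values on these arrays widen the sets and enter their medians.

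Within slides 1, 2 and 3 the probes higher at 24 h had medians of 0.77, 0.66 and 0.66 and the lower ones of -0.67, -0.77 and -0.75, and 4457 probes differed with the slide as a block. The count was 2676 without replicate 1 of 24 h, 2350 without replicate 2 of 24 h and 2333 without replicate 3 of 2 h. Over left-out arrays the 437 returning probes ranged from 228 to 489 and the 158 from 59 to 197, while the 1114 and 949 late probes ranged from 467 to 1332 and from 429 to 1124. In the same order the 4 sets held 90, 87, 221 and 159 probes under spike-in scaling, 222, 79, 535 and 395 with normexp and 189, 98, 283 and 249 without slide 2.

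Spike-in RNA of known amounts, added to every sample, was brighter relative to wheat signal on the treated arrays. The mean log2 signal of 8 spike-in sequences lay above the array's 75th percentile by 2.79 ± 0.12 in the control, 3.12 ± 0.37 in acid, 3.25 ± 0.29 after 2 h in alkaline water and 3.08 ± 0.16 after 24 h (SD, n = 3). The 9 treated arrays exceeded the 3 control arrays by 0.36 on average (exact permutation test over 220 permutations, two-sided p of 0.0455, where the smallest possible is 0.00455). Acid replicate 2, at 2.74, lay below the highest control array, at 2.91, but all 9 treated arrays lay above the control array of their own slide, by 0.019 to 0.806. With the control label permuted within slides (64 permutations), the two-sided p was 0.0469, where the smallest possible is 0.0156. All fold changes given with the 75th percentile are therefore relative to the bulk of wheat signal on each array. The 8 sequences did not rise alike. Sequence n9 lay at 6.39 to 6.68 on the control arrays and at 6.91 to 7.31 on the 24 h arrays. Sequence a22 lay at 1.92 to 2.18 and at 2.03 to 2.22. Spike-in scaling took the mean of all 8 as the offset of an array.

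**Figure D4:**
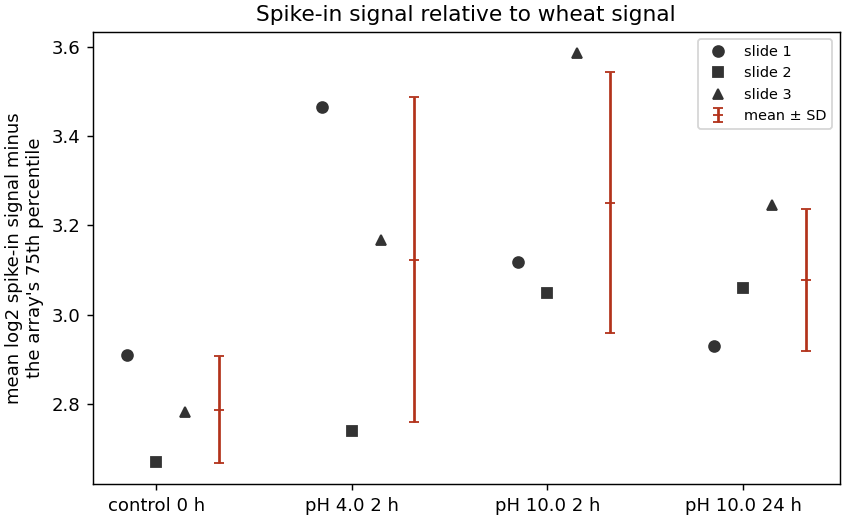
Mean log2 signal of 8 spike-in sequences minus the array's 75th percentile for each of the 12 arrays, with point shapes for the 3 slides and bars for the mean and SD of each group. The control arrays sit between 2.67 and 2.91 and the treated arrays between 2.74 and 3.59.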

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

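The tests of alkaline replicate 1, of array quality weights over other splits, of spike-in scaling and of leaving out slide 2 were chosen after the results were seen. A total of 4 results stood out as differences between groups. The change from the control differed between 24 h and 2 h in alkaline water for 4161 probes in limma's direct test. It differed between alkaline and acid water at 2 h for 38 probes in the same kind of test. In opposite directions went 302 probes between acid at 2 h and alkaline water at 24 h, and 82 probes between 2 h and 24 h in alkaline water. Effects of called probes placed at random gave 138 to 181 and 56 to 98 such probes, and effects of all probes 1443 to 1536 and 1171 to 1303. The former gave fewer calls than observed and the latter more. Neither number is therefore shown to exceed that of independent responses. Of the 171 probes raised in acid and lowered at 24 h, 166 were also lower at 24 h than at 2 h in alkaline water, with median log2 changes of 0.90 in acid, 0.32 at 2 h and -0.795 at 24 h in alkaline water. The 302 ranged from 103 to 427 and the 82 from 30 to 105 over left-out arrays, and they were 37 and 8 under spike-in scaling, 133 and 33 with normexp and 86 and 16 without slide 2.

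That only 38 probes differed directly between alkaline and acid water was weighed against 3 technical explanations. Acid replicate 2 lay apart in the principal component analysis, and leaving it out gave 45 probes. Leaving out an array also costs power, as only 1 probe was called without alkaline replicate 2. The 45 therefore cannot decide whether acid replicate 2 lowers the count. Alkaline replicate 1 is a candidate explanation, since leaving it out gave 1030 probes, more than any other array, and it correlated with the acid arrays at 0.98 and with its own group at 0.977. Low power cannot be told apart from a true likeness for each probe, as 65.7% of simulated 2-fold and 13.1% of 1.5-fold differences were recovered in this comparison. An unadjusted p under 0.05 (limma) was found for 5189 of 30536 probes, a larger share than the 0.05 that chance gives on average. The count of 38 therefore does not show that the other probes were alike. Of the 1030 probes, 91.5% lay on the same side of the acid mean on alkaline replicate 1, which did not enter their selection. Their signed median log2 difference was 0.302 there and 0.761 on replicates 2 and 3. The acid arrays entered both the selection and these values, which raises the share. A true likeness of the early responses in part of the probes stays open beside both arrays. The values of alkaline replicate 1 may come from that sample of roots or from its array.

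The 6 arrays of each comparison make 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many probes. The real counts were 3680 for acid, 1628 for alkaline 2 h and 5618 for alkaline 24 h against the control, 38 for alkaline against acid and 4161 for 24 h against 2 h, and the highest other splits gave 1, 1, 0, 1 and 0. Each other split mixes the groups and puts any true difference into the spread, so few calls there were built in. With array quality weights, alkaline against acid gave 9046 probes for the real split and 7462 for another split, which points to a structure of the arrays under those weights (0.348 for acid replicate 2 and 0.372 for alkaline replicate 1, against 2.67 and 2.28 for the replicates 3 of these groups).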

How the results depend on the processing

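Spike-in scaling and leaving out slide 2 were chosen after seeing the data. Of the values for named probes under alternatives, 193 kept their direction and call, 47 kept the direction and lost the call, and 0 reversed. The naming rule asked for no overlap between the 2 groups, so leaving out an array could not reverse a direction. The slide as a block left the fold changes as they were. Counts are given in the order acid, alkaline 2 h, alkaline 24 h against the control, alkaline against acid, and 24 h against 2 h, and overlaps in the order acid with alkaline 2 h, acid with alkaline 24 h, and alkaline 2 h with 24 h. Main counts were 3680, 1628, 5618, 38 and 4161, and main overlaps 1132, 964 and 754. Counts of changed probes and these 3 overlaps, where run and not listed, stayed within 1.5 times. Normexp gave counts of 1761, 745, 2671, 0 and 2022 and overlaps of 531, 374 and 313. For alkaline against acid, quantile normalization gave 14 and so did the deposited table (14), median scaling 17, an intensity trend 181, and a filter for all 12 arrays 150. No filter on dim probes gave 1081 for alkaline 2 h and 10 for alkaline against acid. Fits to 6 arrays gave 2093 for acid, 908 for alkaline 2 h, 1 for alkaline against acid and 2038 for 24 h against 2 h, with fewer arrays to estimate the spread. Array quality weights gave 11625, 7780, 10413, 9046 and 6509. Asking for at least 2-fold gave 1149, 781 and 1561 against the control and 1271 for 24 h against 2 h, and an adjusted p under 0.01 gave 1365, 541, 1786, 1 and 1435, by construction. Spike-in scaling gave 1106, 582, 1802, 9 and 971 and overlaps of 359, 211 and 219, with medians of all probes at -0.35, -0.498, -0.32, -0.13 and 0.17. The main medians against the control were -0.02, -0.03 and -0.03. Normexp, with its offset, gave log2 changes closer to 0 for all named probes, such as 2.68 in place of 5.87 for A_99_P150147 at 2 h in alkaline water. It ended the calls of A_99_P179251 in both waters, of A_99_P414732, of A_99_P150147 at 2 h (adjusted p of 0.061) and of all named probes in alkaline against acid. Quantile normalization and the deposited table each ended those of A_99_P084200 and A_99_P312611, and leaving out slide 2 those of A_99_P150147 at both times and of all named probes in alkaline against acid. Normexp put the medians against the control at -0.10, -0.10 and -0.12. Without slide 2, counts were 565 for alkaline 2 h, 1343 for alkaline 24 h, 0 for alkaline against acid and 1817 for 24 h against 2 h, and overlaps 449, 297 and 179, from fewer arrays. Leaving out each array gave counts of 1759 to 4139, 685 to 2028, 2555 to 4684, 1 to 1030 and 2333 to 3064, and overlaps of 535 to 1181, 402 to 1102 and 314 to 967. Returning probes (437 raised and 158 lowered at 2 h), late probes (1114 raised, 949 lowered), probes changed in all 3 treated groups (346 raised, 117 lowered) and probes that went opposite ways (302 between acid and 24 h, 82 between the alkaline times) numbered 90, 87, 221, 159, 59, 62, 37 and 8 under spike-in scaling. They numbered 222, 79, 535, 395, 132, 46, 133 and 33 with normexp and 189, 98, 283, 249, 92, 37, 86 and 16 without slide 2. Their lowest numbers over left-out arrays were 228, 59, 467, 429, 173, 31, 103 and 30. Apart from the changes with fewer arrays or stricter thresholds, the cause was not tested.

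With the replicate number, which is also the slide, as a block, the counts were 3999, 1907, 6090, 53 and 4457 and the overlaps 1288, 1135 and 953, and of the named probes only A_99_P084200 lost its call (adjusted p of 0.058, with 0.053 to 0.17 over the alternatives that ended it). Residuals of same-numbered arrays correlated at -0.188 to 0.437, and 9 of the 12 arrays correlated best with their own number, a hint from the data only. Scan date was not run, because all arrays were scanned on 1 day in slide order. The planned gene list tests were not run, because no list had a member. For probes not well above background in a group, folds are lower limits, and signal over background sets that limit. Without control replicate 2 the limit for A_99_P179251 went from 2.31-fold to 1.17-fold in acid and from 2.23-fold to 1.13-fold in alkaline water, and for A_99_P414732 from 2.92-fold to 1.26-fold. Without control replicate 3 those of A_99_P179251 were 3.97-fold and 3.83-fold, and without control replicate 1 that of A_99_P414732 was 4.84-fold. The other limits stayed within 1.5 times over left-out arrays.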

Other observations

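The tests of the shared control arrays, of effects placed at random, of time of day, of the spike-in signal and of spike-in scaling were chosen after the results were seen. Probes called at 2 h in only 1 of the waters mostly moved the same way in the other. The 921 probes raised in acid and not called in alkaline water had a median log2 change of 0.83 in acid and 0.41 in alkaline water, and 94.7% had the same sign in both. The 1626 lowered in acid alone had medians of -0.54 and -0.23, with the same sign in 94.6%. The 338 raised in alkaline water alone had medians of 0.84 there and 0.37 in acid, and the 157 lowered in alkaline water alone -0.76 and -0.37. The direct test called a difference for 17 of the 921, 3 of the 1626, 4 of the 338 and 1 of the 157. The shared control arrays raise the share of equal signs. It was 66.7% over all probes in simulations with no effect, against 70.9% observed, but groups without effects are no reference for groups that changed. In any of these 4 classes it was at most 62.6% with effects of the observed sizes placed on probes at random.

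Part of the probes of the shared early response were also called after a day at pH 10.0. Of the 1132 probes changed the same way at 2 h in both waters, 463 were changed that way at 24 h too, 70 were changed the opposite way, and 547 had moved back from their 2 h level. The 463 were 346 raised and 117 lowered probes, which ranged from 173 to 378 and from 31 to 125 over left-out arrays (173 and 31 without control replicate 3) and were 59 and 62 under spike-in scaling. Both parts also fell by over 1.5 times without control replicate 2 (188 and 70), 2 h alkaline replicate 3 (210 and 44) and acid replicate 3 (223 and 62). The lowered part alone did so without control replicate 1 (56), 2 h alkaline replicate 2 (55), replicate 2 of 24 h (71) and acid replicate 1 (76). Over all 1132 shared probes, the median log2 change in the direction of 2 h was 1.08 in size at 2 h and 0.37 at 24 h.

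The likeness of the early responses to both waters was weighed against 3 explanations. Noise of the shared control arrays as the whole cause would leave no covariance between changes that share no array, and the 6 covariances within different slides were 0.12 to 0.267, with a mean of 0.171 and an SD of 0.0557. A bias with brightness would move whole classes of like brightness, and the largest median shift of any brightness decile was 0.115, against a median size of 1.08 for the shared probes. Whether time of day was the whole cause cannot be decided. The signed median of the shared probes at 24 h was 0.374, above the highest simulated value of 0.0475 for probes back at the control, while 547 had moved back. The only roots of 24 h had stayed in alkaline water and were older. Alkaline water or age could therefore keep these probes off the control level even if time of day had caused the early changes. Time of day, the handling of the seedlings at the change of water, a difference in place on the slide and a common response stay open as hypotheses. No sample moved to fresh water of pH 6.5 was analysed here.

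The lower spike-in signal relative to wheat signal on the control arrays was weighed in the same way. Chance variation between arrays is weakly argued against, as permuting the control label within slides gave a p of 0.0469, although the acid arrays alone spanned 0.728. All 9 treated arrays lay above the control array of their slide, as less total messenger RNA per unit of RNA in treated roots would need. Less messenger RNA alone would also raise all spike-in sequences by a like amount, and the rise at 24 h differed between sequences. Less messenger RNA cannot be told apart from a technical difference in labelling or in the amount of spike-in RNA that goes with place on the slide, because each of the 4 groups had the same place on every slide.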
